A study of Patiria miniata with 16 samples.

How the data were processed

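The study measured gene expression by stranded, paired-end bulk sequencing of polyA RNA from pools of whole embryos of the bat sea star Patiria miniata. Embryos were raised with or without beta-aminopropionitrile (BAPN), an inhibitor of the lysyl oxidase enzymes that cross-link collagen. The authors deposited raw read counts per gene for 16 libraries in 1 table with 27818 genes. Every value in that table was a whole number, and each column was matched to its library by the library name in the labels. The aligner, the counting program and the genome build are not given in the sources used here. Start and end of all 27818 genes equal those of the Pmin_3.0 reference table, whose coordinates and product names are used below. Most product names end in "-like", which marks a name that the annotation transferred by similarity.

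The libraries form 8 groups of 2. They are BAPN from hatched blastula to day 2, BAPN from gastrula to day 3, BAPN from hatched blastula to day 4, BAPN from gastrula to day 4, recovery (BAPN from hatched blastula to day 2, then removed, labelled day 4), and untreated controls of day 2, day 3 and day 4. In each treated group 1 library had 1.2 mM BAPN and the other 0.8 mM, so the 10 treated libraries hold 5 at each dose. The spread within a treated group therefore contains any difference between doses. Gastrula to day 4 and recovery have no labelled control of their own and were compared with the day 4 controls. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

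Total counts ran from 9945801 to 14383817 per library. Of the 27818 genes, 4125 had no count in any library. Genes were kept by edgeR's filter on the 8 groups (minimum count 10, minimum total count 15). This left 17519 genes and removed 10299. Libraries were scaled by TMM, and expression is given as CPM, the counts scaled to a common library total, with a prior count of 2 on the log2 scale. One edgeR quasi-likelihood model with robust dispersions was fitted to all 16 libraries, with 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The standard error (SE) of a log2 change is its size divided by the square root of the F statistic. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

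In all, 13 comparisons were made. They were the mean BAPN effect over the 3 windows with a control of their own, each of the 4 treated windows against the controls of its day, recovery against day 4 controls, recovery against blastula to day 4, the blastula start against the gastrula start at day 4, the day 4 effect minus the day 2 effect of the blastula start, the controls of day 3 against day 2 and of day 4 against day 3, and the tests of dose. Dose was tested across the 10 treated libraries with the group in the model. It was also tested as the dose difference in treated minus that in control libraries, in the 12 libraries of 6 pairs, where the labels name a control for each of 6 treated libraries. The model was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 17519. For a single window it recovered 46% of genes changed 2-fold and 70% of those changed 4-fold, with 14 unchanged genes called. For the mean of 3 windows it recovered 75% and 91%, with 10 unchanged genes called. For dose the shares were 68% and 87%, with 14 unchanged genes called, and for dose against the controls 34% and 72%, with 7 unchanged genes called.

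Before the data were examined, 24 gene lists were fixed as words in product names: germline, nodal and BMP signalling, collagens, collagen-modifying enzymes, other matrix proteins, matrix receptors and adhesion, matrix proteases and inhibitors, Wnt signalling, FGF and VEGF signalling, YAP and mechanotransduction, neurons, muscle, mesenchyme and immune cells, gut, cilia, hydrocoel and coelom regulators, ER chaperones and unfolded protein response, heat shock proteins, xenobiotic and redox enzymes, apoptosis, cell cycle, cytosolic ribosomal proteins, histones, and mitochondrial ribosome and respiratory chain. Products that the words took by mistake were removed after the names had been seen and before any comparison was run. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes. It was tested again with a correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance. Camera p-values were adjusted over the 24 lists of a comparison. The number of members called was also counted with p adjusted over the list alone.

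Named genes were chosen by a rule fixed before the data were examined. For the first 6 comparisons it takes the 10 largest rises and 10 largest falls among called genes with a product name, a mean log2 CPM of at least 1 and both treated libraries on the same side of both controls. It adds up to 4 called members of each list with the smallest p (2 if none was called) and every nanos, DDX4, piwi-like and lysyl oxidase gene. For the other comparisons it takes 5 rises and 5 falls. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Floors cover counting error only. Counts of genes with close paralogs depend on how reads shared between copies were assigned, which these files do not show.

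The alternatives planned before the data were examined were DESeq2's Wald test, DESeq2's size factors in edgeR, no filter, a filter of at least 1 CPM in 4 libraries, dispersions that are not robust, an absolute log2 change of at least 1 required beside the adjusted p, a fit of only the groups compared, an average of 4 windows, the labelled pairs or the dose series as a block, and leaving out each library in turn. Total counts as the only scaling, the counts without rRNA genes, the lists as first written, recovery against day 3 controls and a division of the day 4 controls were added after seeing the data. Shared day 4 controls were checked on 20 simulated data sets with no change, and by giving 1 control library to each comparison, in both divisions, in a fit with 7 residual degrees of freedom. Genes with too few counts for the filter were left out of all tests.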

Results

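Polyadenylated RNA of whole sea star embryos was counted per gene in 16 libraries, 2 in each of 8 groups. Of these groups 5 had received BAPN, an inhibitor of the lysyl oxidases that cross-link collagen in the extracellular matrix, and 3 were untreated controls of day 2, day 3 and day 4. The labels place the work among questions about the collagen matrix and germline gene expression. Total counts per library ran from 9945801 to 14383817. Genes of ribosomal RNA took 0.32% to 0.98% of counts in 13 libraries, 3.2% in day 4 control replicate 2, and 2.02% and 1.34% in the recovery libraries. Changes below are log2 values ± SE from edgeR, with 2 libraries per group. P-values measure only the spread between these libraries, the 2 libraries of a treated group differ in dose, and lower bounds against a group at 0 counts cover counting error only.

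The first principal component held 49% of the variance and separated the 8 libraries collected in BAPN, at scores of -142 to -49.5, from the 6 controls, at 65.1 to 117. The recovery libraries lay with the controls, at 96.6 and 87 on this axis. On the second component, with 16.2% of the variance, they scored 4.1 and -4.3, next to the day 3 controls at 3.6 and 5.7. The day 4 controls scored 75.1 and 78.4 there.

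**Figure D1:**
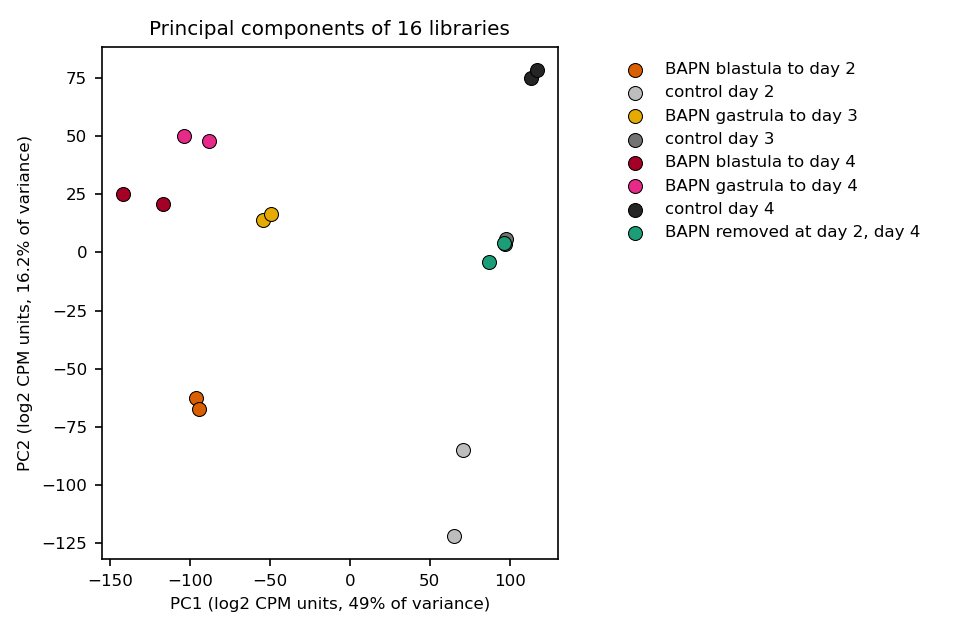
Each point is 1 of 16 libraries on the first (x, 49% of variance) and second (y, 16.2%) principal component of log2 CPM, coloured by group. The libraries collected in BAPN sit at -142 to -49.5 on the x axis, and controls and recovery libraries at 65.1 to 117.

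The broadest comparison asked which genes BAPN changed on average over the 3 windows with a control of their own day. An eIF5A-1-like gene (LOC119746463, a translation factor) rose by 8.64 ± 0.23, from 0.603 to 292 CPM, and an LVN1.2-like gene (LOC119730869) rose from 0.0511 to 166 CPM, with no fold given because its day 2 controls held 0 counts. Some enzymes that act on foreign compounds rose as well. The cytochrome P450 3A6-like gene (LOC119737034, a monooxygenase; scaffold NW_024037069.1, 19907029 to 19913670, Pmin_3.0) rose by 7.03 ± 0.12, from 2.91 to 360 CPM on average (adjusted p = 1.8e-20). A neighbouring 3A24-like copy (LOC119737035) rose by 6.0 ± 0.11, a 3A29-like copy (LOC119725275) by 4.68 ± 0.10, and a multidrug resistance-associated protein 4-like gene (LOC119739678, an efflux pump) by 3.75 ± 0.08. Matrix metalloproteinase-18-like (LOC119735925, a collagenase family member; NW_024037068.1, 1580501 to 1586757) rose by 5.93 ± 0.14, from 16.4 to 660 CPM (adjusted p = 9.4e-17). Macrophage-expressed gene 1 (LOC119725736, a pore-forming immune protein) rose by 5.91 ± 0.15. The striated muscle myosin heavy chain gene (LOC119735028; NW_024037067.1, 7579082 to 7645173) fell by 5.87 ± 0.21, from 408 to 6.41 CPM. PCNA (LOC119732257, the sliding clamp of DNA replication; NW_024037063.1, 1166092 to 1172330) fell by 4.12 ± 0.13, from 309 to 18.2 CPM. Calreticulin-like (LOC119722348, a chaperone of the endoplasmic reticulum; NW_024037053.1, 1414488 to 1425090) fell by 2.72 ± 0.09, from 1590 to 240 CPM (adjusted p = 2e-16). Each of these 11 genes, and each gene named for the mean effect below unless a number is given, moved in its direction in 6 of 6 treated libraries against the controls of their day. Genes named as a largest rise or fall had to meet this condition, so for them it is no separate evidence. Values of single P450 3A, fibrillin, collagen, ribosomal protein and LVN1.2 copies are uncertain, since reads may be shared between copies.

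Among regulators of germ cells, both DDX4 genes, vasa-type RNA helicases, and 1 nanos gene, a translational repressor of germ cells, rose. DDX4 LOC119728304 (NW_024037059.1, 25081276 to 25105512) rose by 1.03 ± 0.09 (adjusted p = 2.7e-09) and DDX4 LOC119742591 (NW_024037073.1, 8264150 to 8299928) by 1.01 ± 0.11 (adjusted p = 4.5e-08). Nanos 3-like LOC119721081 (NW_024037076.1, 20945058 to 20947527) rose by 1.45 ± 0.22 (adjusted p = 6.6e-06). All 3 were higher in 6 of 6 treated libraries. A further nanos gene (LOC119721088) had low counts, at 1.71 against 0.351 CPM, and rose (adjusted p = 0.015, 5 of 6 libraries), with no fold given because its day 4 controls held 0 counts. Of the piwi-like 1 genes, which guard germ cells against transposons, LOC119730361 fell by 0.38 ± 0.07 (4 of 6 libraries; -0.6 with total counts only), and LOC119732162 rose by 0.30 ± 0.08 but by 0.08, not past the test, with total counts as the only scaling. LOC119719434 had low counts, at 1.72 against 3.36 CPM, and fell by 1.17 ± 0.45 (adjusted p = 0.03, 4 of 6 libraries), but did not pass in 6 of the 26 settings. No other piwi-like gene passed. Values of the piwi-like copies are uncertain in the same way. Bicaudal C (LOC119729938, an RNA-binding repressor of translation; NW_024037061.1, 18889006 to 18934069) rose by 2.13 ± 0.08 (adjusted p = 3.1e-15, 6 of 6 libraries). CPEB (LOC119739653, which controls polyadenylation of stored messages) fell by 1.88 ± 0.10 (6 of 6). Of 29 measured germline genes 12 rose and 4 fell over all genes, and the same numbers passed when adjusted over the list alone. Their median was 0.13 but -0.09 with total counts only, their mean was -0.01, and camera gave no call (up, adjusted p = 0.22).

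**Figure D2:**
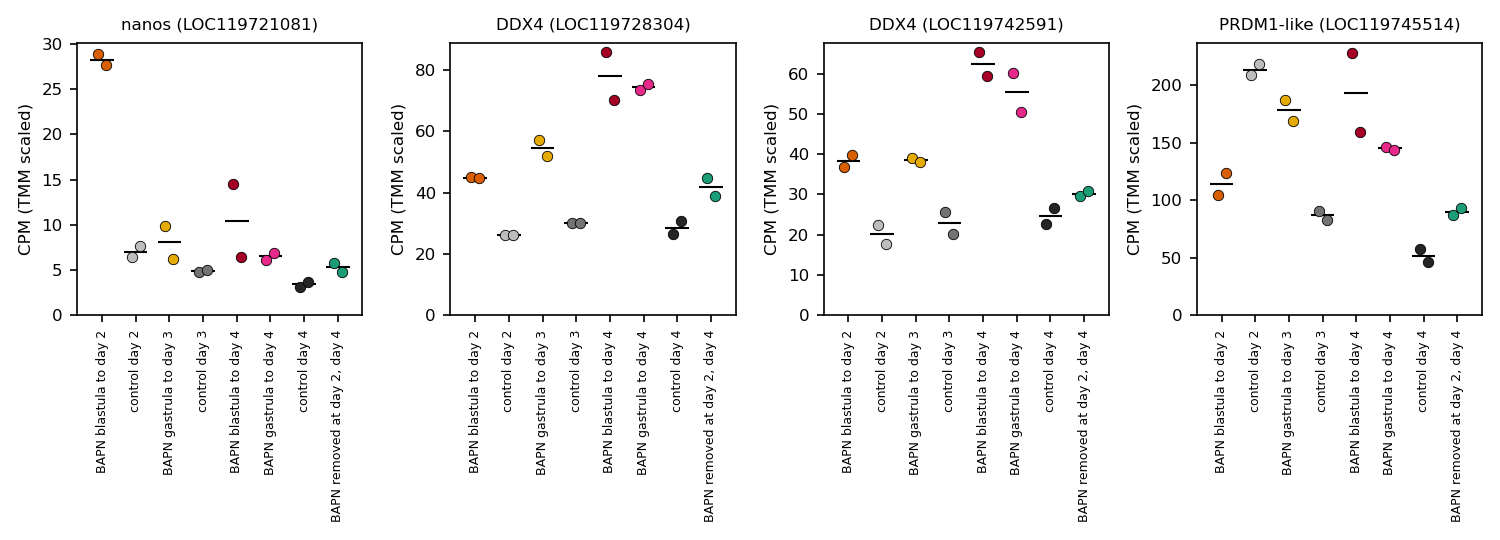
TMM-scaled CPM (y) of the nanos, DDX4 and PRDM1-like genes in each library, by group (x); points are libraries and lines are means of 2. Both DDX4 genes and nanos lay above the controls of the same day in each window, and PRDM1-like was at 114 against 214 CPM at day 2 and 194 against 51.5 CPM at day 4.

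Genes of the matrix did not move as 1 block. Of 28 collagens 4 rose and 11 fell (the same adjusted over the list alone), with a median of -0.61, or -0.59 with genes at 0 held at their bound (camera adjusted p = 0.16). Collagen IV chains LOC119724226 and LOC119724229, of basement membranes, fell by 0.67 ± 0.08 (5 of 6 libraries) and 0.51 ± 0.08 (3 of 6; -0.8 as an average of 4 windows). Collagen alpha-1(I)-like LOC119741733 rose by 2.09 ± 0.29 (4 of 6; 4.13 without day 2 control replicate 1). Among collagen-modifying enzymes 5 rose and 5 fell of 14 (median 0.21, or -0.01 with total counts only; camera adjusted p = 0.82). A lysyl oxidase homolog 2A-like gene (LOC119735518; NW_024037048.1, 2990736 to 3009565), of the enzyme family BAPN inhibits, fell by 1.46 ± 0.29 (adjusted p = 1.9e-04, 6 of 6 libraries). A further lysyl oxidase gene (LOC119738367) had 0.81 ± 0.56 (higher in 3 of 6 libraries) and did not pass (adjusted p = 0.22), but had -0.53 without blastula to day 2 replicate 1 and passed without replicate 2 (1.12). BMP1 homolog LOC119731558, a procollagen proteinase, rose by 0.80 ± 0.08 (6 of 6). Of 90 other matrix proteins 32 rose and 27 fell (median 0.35, 0.28 with bounds; camera adjusted p = 0.18). These included fibrillin-2-like LOC119745555, of microfibrils, at 2.16 ± 0.07, from 241 to 1060 CPM. Matrix receptors had 19 rises and 7 falls of 38 (median 0.48, 0.36 with bounds; camera up, adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation). Discoidin domain receptor 2-like (LOC119734382, a collagen receptor kinase) rose by 2.59 ± 0.08. Of 36 matrix proteases and inhibitors 17 rose and 10 fell, or 18 and 10 adjusted over the list alone (median 0.63; camera adjusted p = 0.072). ADAMTS-like 5 (LOC119745898) fell by 3.77 ± 0.12. Of 35 YAP and mechanotransduction genes 12 rose and 11 fell (median -0.17 and mean -0.19, while camera pointed up, adjusted p = 0.97). Vinculin-like (LOC119725907, a linker of adhesions to actin) fell by 1.91 ± 0.08.

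Signalling genes changed in both directions. Of 31 nodal and BMP genes 14 rose and 11 fell (median 0.06, or -0.16 with total counts only; mean -0.26, while camera pointed up, adjusted p = 0.59). Smad5-like (LOC119727472, a transducer of BMP signals) rose by 2.65 ± 0.07, and kielin/chordin-like (LOC119721939, a secreted BMP modulator) fell by 1.48 ± 0.09. Of 33 Wnt genes 14 rose and 9 fell, or 15 and 9 adjusted over the list alone (median 0.34; camera adjusted p = 0.14), among them Wnt-8b-like (LOC119730682) at 3.18 ± 0.14 and Wnt-16-like (LOC119726703) at 2.74 ± 0.10. Of 20 FGF and VEGF genes 10 rose and 6 fell, or 10 and 7 adjusted over the list alone (median 0.68, 0.55 with bounds; camera adjusted p = 0.11). VEGF receptor 1-like (LOC119719573) rose by 2.19 ± 0.09.

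Among the tissue lists, camera called cilia and muscle genes. Of 107 cilia genes 68 fell and 4 rose (median -0.66; camera adjusted p = 4.9e-07, and adjusted p = 0.24 with an estimated correlation), the same numbers as adjusted over the list alone. Axonemal dynein heavy chain 2 (LOC119728258, a motor of cilia) fell by 1.56 ± 0.09 and radial spoke head 9 (LOC119742585) by 1.80 ± 0.11, while CFAP251 (LOC119721168) rose by 2.38 ± 0.08. Of 30 muscle genes 17 fell and 3 rose (median -1.08; camera adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation). Troponin I-like (LOC119721916) fell by 1.24 ± 0.08. Of 30 neuronal genes 17 fell and 4 rose, or 18 and 4 adjusted over the list alone (median -0.8; camera adjusted p = 0.067). Neurexin-1-like (LOC119743568, of synapses) fell by 2.85 ± 0.21, and tryptophan 5-hydroxylase 1-like (LOC119740445, of serotonin synthesis) rose by 2.12 ± 0.14. Of 45 gut genes 17 fell and 11 rose (median -0.97, -1.11 with bounds; camera adjusted p = 0.1). Of 27 hydrocoel and coelom regulators 15 fell and 8 rose (median -1.36, -1.29 with bounds; camera adjusted p = 0.1). Pax-6-like (LOC119738408) fell by 2.09 ± 0.13 and FoxF1-like (LOC119737216) rose by 3.00 ± 0.14. Of 98 mesenchyme and immune genes 30 rose and 23 fell, or 29 and 23 adjusted over the list alone (median 0.16, or -0.06 with total counts only; camera adjusted p = 0.22).

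Among lists of cell growth and stress, 31 of 38 cell cycle genes fell and 2 rose (median -1.23; camera adjusted p = 2.3e-07, and adjusted p = 0.24 with an estimated correlation). Thymidylate synthase (LOC119724700, of DNA precursor synthesis) fell by 3.70 ± 0.12, and mcm5 (LOC119741031, of the replicative helicase) by 3.29 ± 0.12. Of 22 ER chaperones 16 fell and 3 rose (median -0.95; camera adjusted p = 0.001, and adjusted p = 0.24 with an estimated correlation). Of 19 heat shock genes 12 fell and 4 rose (median -0.67; camera adjusted p = 0.072). Of 315 xenobiotic and redox enzymes 148 fell and 85 rose, or 148 and 86 adjusted over the list alone (median -0.56, -0.55 with bounds; camera adjusted p = 0.12), while the P450 3A copies named above rose. Of 32 apoptosis genes 13 rose and 7 fell (median 0.32; camera adjusted p = 0.1), and bcl-2-like protein 1 (LOC119742144, which blocks cell death) rose by 2.56 ± 0.09. Of 148 mitochondrial genes 61 fell and 17 rose (median -0.17; camera adjusted p = 0.0058, and adjusted p = 0.42 with an estimated correlation). Of 70 cytosolic ribosomal proteins 42 rose and 1 fell, but 9 rose and 7 fell with total counts only (median 0.23 and 0.01; camera adjusted p = 0.0012, and adjusted p = 0.66 with an estimated correlation). Of 39 histones 9 rose and 8 fell, or 8 and 6 adjusted over the list alone (median -0.37, -0.13 with bounds, mean -0.36, while camera pointed up, adjusted p = 0.97). Where only 1 pair of counts is given for a list, both adjustments gave it.

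In total 10207 of 17519 genes were called for the mean effect, 4926 higher and 5281 lower. With total counts as the only scaling 3830 were higher and 6656 lower, and the median change of all genes moved from -0.07 to -0.29. TMM factors were 0.874 to 0.987 in the libraries collected in BAPN and 0.994 to 1.143 in controls.

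**Figure D3:**
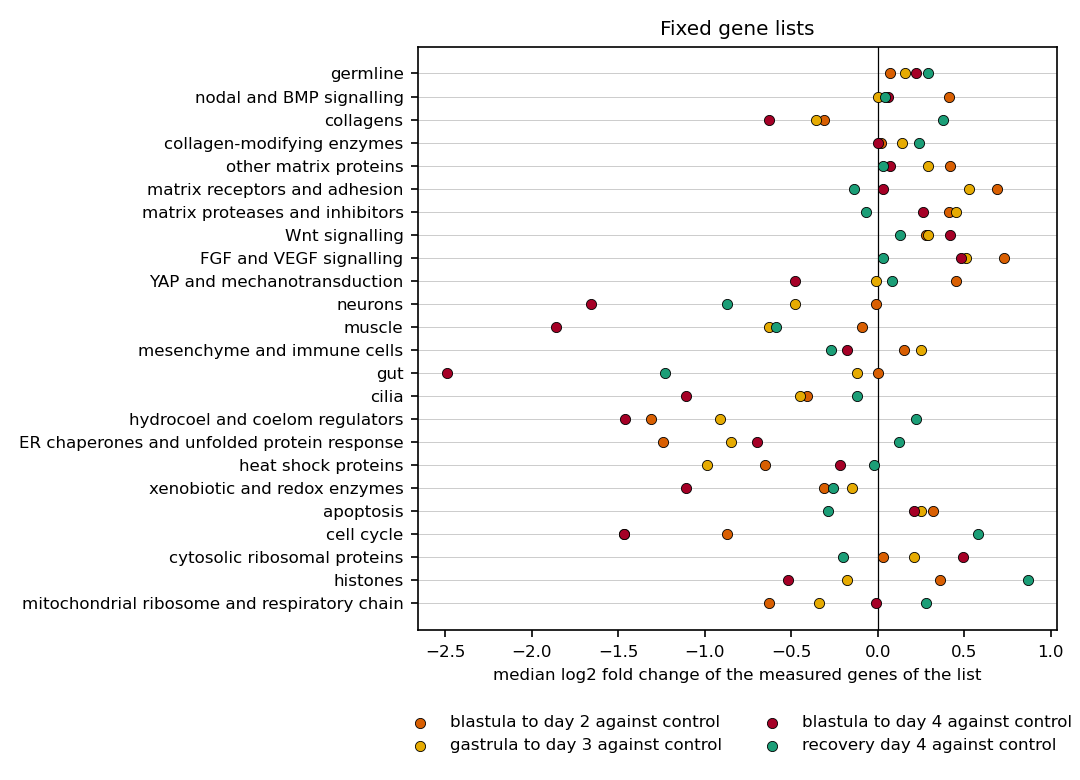
Median log2 change (x) of the measured genes of each fixed list (y) in the 3 windows with their own controls and in recovery, 1 point per comparison. Cilia genes lay below 0 in each, gut genes reached -2.49 and muscle genes -1.86 in blastula to day 4, and with total counts only the germline, ribosomal and some other medians near 0 changed sign.

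Embryos kept in BAPN from hatched blastula to day 2 were compared with day 2 controls. An LVN1.2-like gene (LOC119730869) was at least 721-fold higher. In the windows that follow, each gene named as risen or fallen lay on that side in 2 of 2 treated libraries. For the largest rises and falls this was a condition of being named. Engrailed-1a-like (LOC119718926, a homeobox regulator; NW_024037074.1, 17671360 to 17687004) was at least 577-fold higher, at 77.1 ± 11.5 (SD, n = 2) against 0 CPM. Caspase-7-like (LOC119735747, an executioner of apoptosis) was at least 245-fold higher, and Hox-A5-like (LOC119728716, a regulator of axial position) at least 154-fold lower. MMP-18-like rose by 8.02 ± 0.28 and P450 3A6-like by 7.63 ± 0.22 (adjusted p = 6.4e-16, 2 of 2 libraries). Wnt-7b-like (LOC119738535) fell by 4.32 ± 0.37, FoxF1-B-like (LOC119739333) by 3.56 ± 0.23 and Pax-6-like by 3.02 ± 0.24. Nanos 3-like rose by 2.01 ± 0.37 (adjusted p = 1.6e-04, 28.3 ± 0.81 against 7.02 ± 0.858 CPM, SD, n = 2), DDX4 LOC119728304 by 0.78 ± 0.16 and DDX4 LOC119742591 by 0.93 ± 0.19. PRDM1-like (LOC119745514, a transcriptional repressor of the Blimp1 family; NW_024037074.1, 10779530 to 10803410) fell by 0.91 ± 0.15.

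At day 2, 14 of 22 ER chaperones fell and 1 rose, or 14 and 2 adjusted over the list alone (median -1.24; camera adjusted p = 1.3e-05). A BiP-like gene (LOC119720212) fell by 2.61 ± 0.19 and PDIA6 (LOC119724894, a disulfide isomerase) by 3.09 ± 0.18. Of 148 mitochondrial genes 67 fell and 2 rose, or 69 and 3 adjusted over the list alone (median -0.63; camera adjusted p = 4.3e-08). Of 38 cell cycle genes 23 fell and 1 rose, or 25 and 1 adjusted over the list alone (median -0.87; camera adjusted p = 1.3e-05). Matrix receptors rose in 18 and fell in 4 of 38, or 20 and 4 adjusted over the list alone (median 0.69; camera adjusted p = 0.0015). For these 4 lists adjusted p = 0.31 with an estimated correlation. Cilia genes fell in 40 and rose in 6 of 107, or 43 and 7 adjusted over the list alone (median -0.41; camera adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). The lysyl oxidase homolog 2A-like gene fell by 1.60 ± 0.50 (adjusted p = 0.014), a call lost without treated replicate 1 (-1.62) or replicate 2 (-1.63). In this window 7264 genes were called, 3817 higher and 3447 lower, or 2978 and 4679 with total counts only (median of all genes -0.01 and -0.26).

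BAPN from gastrula to day 3 was compared with day 3 controls. POU4F2-like (LOC119727541, a regulator of sensory neurons) was at least 328-fold lower and the MNX homeobox gene (LOC119721048, of motor neurons and gut) at least 84.5-fold lower. Among transporters, solute carrier 22 member 13-like (LOC119745641) was at least 76.2-fold lower and monocarboxylate transporter 13-like (LOC119728891) at least 60.4-fold lower. Of 30 neuronal genes 4 rose and 5 fell (median -0.48; camera adjusted p = 0.42), with a vesicular glutamate transporter gene (LOC119726821) up by 2.45 ± 0.26 and synaptotagmin-16-like (LOC119742890) down, at -1.13 ± 0.12. Pituitary homeobox x-like (LOC119731189, of left-right asymmetry) fell by 5.42 ± 0.46, and myosin heavy chain by 4.09 ± 0.27, to 14.8 ± 0.153 against 252 ± 13.3 CPM (SD, n = 2). Histamine N-methyltransferase-like (LOC119730557) rose by 8.86 ± 0.37, P450 3A24-like by 6.47 ± 0.19, Wnt-16-like by 3.53 ± 0.18 and fibrillin-1-like (LOC119736511) by 2.58 ± 0.16. PRDM1-like rose by 1.04 ± 0.15 here. DDX4 LOC119728304 rose by 0.86 ± 0.16, and LOC119742591 by 0.75 ± 0.18, a call lost without day 3 control replicate 2 (0.58). Nanos 3-like had 0.73 ± 0.38 and did not pass (adjusted p = 0.16). The lysyl oxidase homolog 2A-like gene LOC119735518 had -1.32 ± 0.51 and did not pass (adjusted p = 0.054), but passed in 11 of 26 alternative settings, where its change ran from -2.11 to -0.81.

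In this window 30 of 38 cell cycle genes fell and 2 rose, or 31 and 3 adjusted over the list alone (median -1.47; camera adjusted p = 4.4e-11). ER chaperones fell in 15 and rose in 1 of 22, or 16 and 3 adjusted over the list alone (median -0.85; camera adjusted p = 1.3e-05). Muscle genes fell in 12 and rose in 0 of 30, or 15 and 0 adjusted over the list alone (median -0.63; camera adjusted p = 0.0011). For these 3 lists adjusted p = 0.19 with an estimated correlation. Cilia genes fell in 39 and rose in 2 of 107, or 40 and 2 adjusted over the list alone (median -0.45; camera adjusted p = 5.1e-05, and adjusted p = 0.33 with an estimated correlation). Mesenchyme and immune genes rose in 26 and fell in 6 of 98 (median 0.25, 0.27 with bounds; camera adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation). In all 5633 genes were called, 2992 higher and 2641 lower, or 2313 and 3705 with total counts only (median of all genes -0.03 and -0.25).

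BAPN from hatched blastula to day 4 gave more calls than the 2 shorter windows, 9054, of which 4275 were higher and 4779 lower. An acetylcholine receptor subunit gene (unc-38-like, LOC119741163, an ion channel of synapses) was at least 1390-fold lower than in day 4 controls, and a GABA transporter-like gene (LOC119719817) at least 608-fold lower. Fatty acid-binding protein 2-like (LOC119732604, of gut epithelium) was at least 886-fold lower. Myosin heavy chain fell by 7.81 ± 0.33, to 4.22 ± 2.68 against 961 ± 148 CPM (SD, n = 2), and neurexin-1-like by 6.72 ± 0.41. Laminin beta-1-like (LOC119721873, of basement membranes) fell by 2.23 ± 0.15, and the collagen IV chains LOC119724226 and LOC119724229 by 1.86 ± 0.14 and 1.67 ± 0.14. An FGF receptor 3-like gene (LOC119735717) rose by 5.17 ± 0.39, Wnt-8b-like by 3.93 ± 0.25 and Smad5-like by 3.04 ± 0.13. DDX4 LOC119728304 rose by 1.45 ± 0.16 and LOC119742591 by 1.34 ± 0.19 (2 of 2 libraries each). Nanos 3-like rose by 1.62 ± 0.39 (adjusted p = 0.0015), a call lost without treated replicate 1 (0.93). PRDM1-like rose by 1.91 ± 0.16 and bicaudal C by 2.52 ± 0.15.

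In that window 19 of 30 neuronal genes fell and 1 rose, or 21 and 1 adjusted over the list alone (median -1.66; camera adjusted p = 9.9e-05). This call held, at adjusted p = 0.031 with an estimated correlation. Muscle genes fell in 21 and rose in 3 of 30 (median -1.86; camera adjusted p = 8.1e-05) and gut genes fell in 21 and rose in 9 of 45, or 22 and 9 adjusted over the list alone (median -2.49; camera adjusted p = 0.022). Both had adjusted p = 0.083 with an estimated correlation. Cilia genes fell in 67 and rose in 5 of 107, or 68 and 6 adjusted over the list alone (median -1.11, -1.15 with bounds; camera adjusted p = 1.2e-07, and adjusted p = 0.29 with an estimated correlation). Axonemal dynein heavy chain 5 (LOC119745907) fell by 2.78 ± 0.17. Ribosomal proteins rose in 49 of 70 and in 28 with total counts only, where 1 fell (median 0.49; camera adjusted p = 5.9e-06, and adjusted p = 0.69 with an estimated correlation). Of 29 germline genes 11 rose and 3 fell (median 0.22, 0.3 with bounds, 0.02 with total counts only; camera adjusted p = 0.2). The lysyl oxidase homolog 2A-like gene fell by 1.46 ± 0.50 (adjusted p = 0.02), a call lost without treated replicate 2 (-1.27) or day 4 control replicate 2 (-1.23). The other lysyl oxidase gene (LOC119738367) rose by 3.51 ± 1.05 (adjusted p = 0.0081), a call lost without day 4 control replicate 1 (3.00). With total counts only the median of all genes moved from -0.1 to -0.3.

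**Figure D4:**
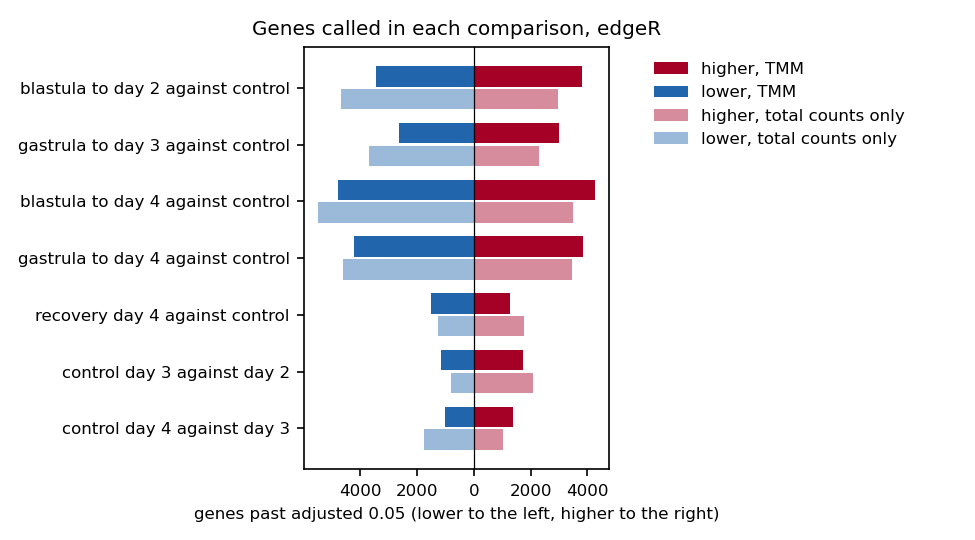
Genes past an adjusted p of 0.05 in edgeR (x, higher to the right and lower to the left) in 7 comparisons (y), with TMM scaling (dark) and total counts as the only scaling (light). For blastula to day 2, 3817 genes were higher and 3447 lower with TMM, against 2978 and 4679 with total counts only.

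Treatment from gastrula to day 4 was also compared with day 4 controls. A phosphate transporter 2-like gene (LOC119724507) was at least 2030-fold lower. Among digestive enzymes, aqualysin-1-like (LOC119740142, a protease) was at least 1640-fold lower and lactase-phlorizin hydrolase-like (LOC119742045) at least 1490-fold lower, and alpha-amylase 4-like (LOC119725945) fell by 2.65 ± 0.27. Troponin T (LOC119721862, of muscle) was at least 395-fold lower. SPARC-like (LOC119731302, a collagen-binding protein) fell by 2.66 ± 0.21. DDX4 LOC119728304 rose by 1.38 ± 0.16 and LOC119742591 by 1.16 ± 0.19. Nanos 3-like had 0.93 ± 0.39, not past the test (adjusted p = 0.058), and passed in 3 of 25 alternative settings, without day 2 control replicate 1 (0.96) and without blastula to day 4 replicate 1 (0.94) or replicate 2 (0.93). The lysyl oxidase homolog 2A-like gene fell by 3.14 ± 0.56 (adjusted p = 7.9e-05; -5.17 without treated replicate 2). Of 107 cilia genes 70 fell and 3 rose, or 72 and 3 adjusted over the list alone (median -0.97; camera adjusted p = 5e-09), and of 38 cell cycle genes 33 fell and 1 rose, or 34 and 1 adjusted over the list alone (median -2.03; camera adjusted p = 1.1e-09). Both had adjusted p = 0.18 with an estimated correlation. Muscle genes fell in 16 and rose in 0 of 30 (median -1.56; camera adjusted p = 5.6e-05, and adjusted p = 0.09 with an estimated correlation). In all 8076 genes were called, 3841 higher and 4235 lower.

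At day 4 the blastula and gastrula starts differed in 2479 genes, 1105 higher and 1374 lower with the blastula start. The earlier start also meant a longer exposure to BAPN, and the design does not separate start from length. Ribosomal proteins were higher with the blastula start in 55 and lower in 0 of 70, or 65 and 0 adjusted over the list alone (median 0.58; camera adjusted p = 2.1e-19, and adjusted p = 0.47 with an estimated correlation). ER chaperones were higher in 7 and lower in 0 of 22, or 8 and 0 adjusted over the list alone (median 0.3; camera adjusted p = 0.0029, and adjusted p = 0.47 with an estimated correlation). Retinol dehydrogenase 8-like (LOC119738128) was at least 21.1-fold lower, with low counts. With total counts only 781 genes were higher and 1773 lower, a shift of the overall median from 0 to -0.1. The count fell to 1386 when only the groups compared were fitted, to 1262 without blastula to day 4 replicate 1 and to 1522 without gastrula to day 4 replicate 2.

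The effect of the blastula start at day 4 minus that at day 2 differed from 0 for 4815 genes, 2123 upward and 2692 downward. An acetylcholine receptor alpha-10-like gene (LOC119741915; NW_024037072.1, 19382547 to 19397458) had 41.7 ± 3.59 CPM (SD, n = 2) in day 4 controls and 0 in blastula to day 4, against 0 in day 2 controls and 0.517 in blastula to day 2. Macrophage migration inhibitory factor-like (MIF-like, LOC119730519, a cytokine; NW_024037061.1, 8274776 to 8279506) had 303 ± 1.94 against 4.1 ± 1 CPM at day 2 and 131 ± 33.7 against 374 ± 60.3 CPM at day 4. Neuronal genes had 12 downward and 2 upward differences of 30 (median -2.41; camera adjusted p = 3.6e-05), held at adjusted p = 0.02 with an estimated correlation. Muscle genes had 13 downward and 0 upward of 30, or 13 and 1 adjusted over the list alone (median -1.28; camera adjusted p = 6.1e-05, and adjusted p = 0.066 with an estimated correlation). Cilia genes had 43 downward and 1 upward of 107, or 45 and 1 adjusted over the list alone (median -0.62; camera adjusted p = 0.00012, and adjusted p = 0.35 with an estimated correlation). Mitochondrial genes had 45 upward and 3 downward of 148, or 50 and 4 adjusted over the list alone (median 0.56; camera adjusted p = 1.5e-06, and adjusted p = 0.35 with an estimated correlation).

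Embryos moved out of BAPN at day 2 and labelled as day 4 embryos were compared first with day 4 controls. MIF-like fell by 8.24 ± 0.28, to 1.23 ± 0.36 against 374 ± 60.3 CPM (SD, n = 2; adjusted p = 1.1e-13, 2 of 2 libraries). C-ets-1-like (LOC119741492, a regulator of mesenchyme) fell by 3.49 ± 0.16 and flavin-containing monooxygenase 5-like (LOC119746042) by 4.59 ± 0.16. Nodal (LOC119731756, a signal of left-right and oral-aboral axes; NW_024037063.1, 5767799 to 5772676) rose by 1.60 ± 0.21, to 78.3 ± 15.7 against 25.8 ± 5.39 CPM. Univin (LOC119741587, a TGF-beta ligand) rose by 1.93 ± 0.21 and lefty-like (LOC119746331, an inhibitor of nodal) by 1.76 ± 0.32. Follistatin-related 5-like (LOC119732438), of the same nodal and BMP list, fell by 2.8 ± 0.3, and the median of that list was 0.04. A vesicular glutamate transporter gene (LOC119726821) fell by 2.83 ± 0.28, choline acetyltransferase-like (LOC119731317, of acetylcholine synthesis) by 4.76 ± 0.72 and myosin heavy chain by 1.67 ± 0.23. DDX4 LOC119728304 rose by 0.55 ± 0.16 (adjusted p = 0.02), a call lost without day 4 control replicate 1 or recovery replicate 1 (0.46 each). The other DDX4 gene (0.29) and nanos 3-like (0.63) did not pass. Piwi-like 1 LOC119730361 rose by 0.49 ± 0.12, a call lost without day 4 control replicate 1 (0.47) or recovery replicate 2 (0.38).

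In recovery against day 4 controls 11 of 30 neuronal genes fell and 0 rose (median -0.87; camera adjusted p = 7.2e-05), and 15 of 45 gut genes fell and 2 rose, or 20 and 2 adjusted over the list alone (median -1.23; camera adjusted p = 3e-05). Both calls held, at adjusted p = 0.013 with an estimated correlation. Cell cycle genes rose in 17 and fell in 1 of 38, or 21 and 1 adjusted over the list alone (median 0.58; camera adjusted p = 4.1e-06, and adjusted p = 0.22 with an estimated correlation). Polo-like kinase 1 (LOC119725776, of mitosis) rose by 1.17 ± 0.16. Of 29 germline genes 5 rose and 0 fell (median 0.29, 0.27 with bounds; camera adjusted p = 0.0066, and adjusted p = 0.099 with an estimated correlation). Pumilio 3-like (LOC119737303) rose by 0.82 ± 0.14. In all 2789 genes were called, 1274 higher and 1515 lower, or 1767 and 1260 with total counts only (median of all genes -0.01 and 0.09). The count was 5240 when only the groups compared were fitted. The count fell to 1714 and 1559 without day 4 control replicate 1 and replicate 2, and to 1782 and 1575 without recovery replicate 1 and replicate 2.

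Against day 3 controls, a comparison chosen after seeing the correlations between libraries, the recovery libraries differed in 114 genes, 51 higher and 63 lower. The unadjusted p lay under 0.05 for 1071 genes. This comparison was run only in the fit of all 16 libraries, so how its count moves in other settings is not known. MIF-like fell by 4.93 ± 0.28 (adjusted p = 2.9e-09), an SPDEF-like ETS factor (LOC119719393) by 4.16 ± 0.24 and C-ets-1-like by 1.66 ± 0.16. An LVN1.2-like gene (LOC119738332) rose by 3.83 ± 0.25, and its copies make the value uncertain. P450 3A6-like rose by 1.41 ± 0.22 (adjusted p = 0.00081). These genes were named after their values were seen. Spearman correlations across genes, which are not independent replicates, were 0.979 to 0.983 between recovery and day 3 control libraries and 0.938 to 0.946 between recovery and day 4 control libraries. The day of collection is known only from the labels, and every comparison of recovery with day 4 libraries rests on it.

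Compared with embryos left in BAPN to day 4, recovery embryos had 4436 genes higher and 4085 lower, or 5734 and 3069 with total counts only (median of all genes 0.12 and 0.43). The unc-38-like receptor gene was at least 505-fold higher and the GABA transporter-like gene at least 408-fold higher. An aspartic proteinase A2-like gene (LOC119730850) was at least 515-fold lower. Cilia genes rose in 62 and fell in 4 of 107 (median 1.02, 0.98 with bounds; camera adjusted p = 4.1e-07, and adjusted p = 0.21 with an estimated correlation). Cell cycle genes rose in 32 and fell in 1 of 38 (median 2.16, 2.11 with bounds; camera adjusted p = 1.3e-09, and adjusted p = 0.21 with an estimated correlation). Ribosomal proteins fell in 63 and rose in 0 of 70, or 64 and 1 adjusted over the list alone (median -0.67; camera adjusted p = 1.3e-09, and adjusted p = 0.61 with an estimated correlation). Of the genes called in blastula to day 4, 77.1% were called in the opposite direction between recovery and blastula to day 4, and both calls use the blastula to day 4 libraries.

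Control embryos alone show which genes changed with age. From day 2 to day 3 muscle genes rose in 13 and fell in 0 of 30, or 15 and 1 adjusted over the list alone (median 1.69, 1.33 with bounds; camera adjusted p = 3e-07). Neuronal genes rose in 7 and fell in 0 of 30, or 10 and 1 adjusted over the list alone (median 0.9; camera adjusted p = 0.00057). Both calls held, at adjusted p = 0.031 with an estimated correlation. A GABA receptor subunit gene (LOC119727692) was at least 84.6-fold higher, and a late H1-gamma histone gene (LOC119735919) fell by 3.53 ± 0.37. From day 3 to day 4 gut genes rose in 12 and fell in 2 of 45, or 15 and 4 adjusted over the list alone (median 0.8, 0.73 with bounds; camera adjusted p = 0.00015), and neuronal genes rose in 8 and fell in 0 of 30, or 9 and 0 adjusted over the list alone (median 0.86; camera adjusted p = 0.00017). Both calls held, at adjusted p = 0.017 with an estimated correlation. Aqualysin-1-like rose by 7.62 ± 0.66, from 1.07 to 214 CPM, and a pancreatic lipase-related 2-like gene (LOC119740278) was at least 298-fold higher. Day 3 against day 2 called 1728 genes higher and 1148 lower, or 2100 and 806 with total counts only, and 1476 in all without day 2 control replicate 2, 1372 without day 3 control replicate 1 and 1340 without its replicate 2. Day 4 against day 3 called 1392 higher and 1015 lower, or 1030 and 1770 with total counts only. Its total was 5895 when only the groups compared were fitted, 1205 and 1218 without day 3 control replicates 1 and 2, and 1392 and 1240 without day 4 control replicates 1 and 2. Medians of all genes moved from 0.06 to 0.16 and from 0.01 to -0.15 between these scalings.

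Between 1.2 and 0.8 mM, 4 genes differed across the 10 treated libraries. Each dose may come from its own culture, which this test alone cannot tell from dose. All 4 genes were higher at 1.2 mM in 5 of 5 windows. They were dnaJ B4-like (LOC119722491, a co-chaperone) at 1.17 ± 0.17 (adjusted p = 0.038), BANP-like (LOC119737625, a nuclear DNA-binding protein) at 0.82 ± 0.13 (adjusted p = 0.011), RNF217 (LOC119724646, a ubiquitin ligase) at 0.67 ± 0.11 (adjusted p = 0.038) and an uncharacterized gene (LOC119732483) at 0.87 ± 0.13 (adjusted p = 0.011). The last was named after its values were seen. Without any 1 library of the 4 windows kept in BAPN, dnaJ B4-like (1.05 to 1.2) and RNF217 (0.56 to 0.7) were no longer called, and neither was BANP-like (0.76 to 0.86) except without gastrula to day 3 replicate 2. With total counts only, dnaJ B4-like (1.16) and RNF217 (0.66) did not pass. The count was 0 without either blastula to day 2 library, either blastula to day 4 library or gastrula to day 4 replicate 2, 1 without gastrula to day 4 replicate 1, and 14 without either recovery library. The count was 55 with DESeq2, 126 with no filter on low counts and 2 with total counts only. An unadjusted p under 0.05 was seen for 1229 genes, where 876 were expected by chance. With the difference of the controls named for them subtracted, edgeR called 0 genes, 760 had an unadjusted p under 0.05, DESeq2 called 3, and edgeR with no filter called 72. In that edgeR test dnaJ B4-like had 1.51 (adjusted p = 0.055), BANP-like 0.93 and RNF217 0.68 (adjusted p = 0.99 each). The uncharacterized gene had 1.26 (adjusted p = 0.88). The edgeR count was 1 without either day 2 control. Among 7429 genes changed by BAPN with a mean log2 CPM of at least 3, the median absolute difference between doses was 0.11, with a median SE of 0.13, and the median absolute BAPN change was 0.87. Ribosomal proteins (median 0.1, camera adjusted p = 0.00032), histones (median -0.38, adjusted p = 0.028) and cilia genes (median -0.11, adjusted p = 0.029) were called between doses, each at adjusted p = 0.65 with an estimated correlation.

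Overlaps show how far windows shared genes. In all 3 windows with their own controls 2048 genes rose, where 159 were expected from independent calls, and 1529 fell, where 142 were expected. At least 1 window called 11433 genes. Blastula to day 2 and gastrula to day 3, which share no library, had 4294 genes called the same way, 2462 higher and 1832 lower (652 and 520 expected), and their changes had r = 0.6 across genes. Blastula to day 2 and blastula to day 4 had 4673 called the same way and 525 in opposite ways. The blastula and gastrula starts at day 4 share their controls and had 6828 genes called the same way (3288 higher, 937 expected; 3540 lower, 1155 expected), with r = 0.83 and a covariance of 5.01. In 20 simulated data sets with no change these 2 comparisons had r = 0.49, a covariance of 0.29 and at most 1 gene called the same way in both. Shared controls alone thus gave much of r there, but neither the number of shared calls nor the covariance seen in the data. They may still add a part of the overlap. With 1 control library for each comparison, in the 2 possible divisions, 5304 and 5353 genes were called the same way, with r = 0.75 and 0.77 and covariances of 4.9 and 4.95. Gastrula to day 3 and gastrula to day 4, which share no library, had 4703 called the same way (2494 higher, 656 expected; 2209 lower, 638 expected), with r = 0.72. Recovery and blastula to day 4, with the same shared controls, had 1589 called the same way (695 higher, 311 expected; 894 lower, 413 expected) and 573 in opposite ways, with r = 0.42 and a covariance of 1.34, against 0.5 and 0.29 in the simulations. With the controls divided, 963 and 875 were called the same way and 317 and 310 in opposite ways, with covariances of 1.22 and 1.2. These correlations are across genes, which are not independent replicates.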

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

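The tests of a factor shared by all genes, of a loss of other cells, of germ cell number and of an earlier stage, the scaling by total counts, the counts without rRNA genes and the comparison with day 3 controls were chosen after results had been seen.

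The effect of BAPN from hatched blastula was measured at day 2 and at day 4, and a test of the difference between the 2 effects singled out the following results. It called 4815 genes, of which 525 were called in opposite directions at the 2 days. Of the 525, the 5 that belong to the germline, collagen, collagen-modifying or nodal and BMP lists are given here. PRDM1-like (LOC119745514), a transcriptional repressor, fell by 0.91 at day 2 and rose by 1.91 at day 4, a difference of 2.82 ± 0.22 (SE, adjusted p = 8.5e-09). Pumilio 3-like (LOC119737303), an RNA-binding protein, fell by 0.48 and rose by 1.14, a difference of 1.61 ± 0.2 (adjusted p = 2.7e-06). Tudor 6-like (LOC119739966), of germ granules, fell by 0.52 and rose by 0.49, a difference of 1.01 ± 0.26 (adjusted p = 0.0054). Tolloid-like 1 (LOC119745357), a proteinase of procollagen and chordin, rose by 0.93 and fell by 0.71, a difference of -1.64 ± 0.31 (adjusted p = 0.00045). Collagen alpha-1(I)-like (LOC119732002) rose by 0.73 and fell by 0.57, a difference of -1.3 ± 0.25 (adjusted p = 0.00054). In each of these genes the 2 treated libraries of a day lay on the side given for that day.

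The first pattern weighed is the fall of cilia genes, whose median was -0.66 over the 3 windows. Gene length as the cause is argued against, since 10000 random lists matched on length and expression had a median of 0.07, none was as low (permutation p = 1e-04, the smallest they can give) and the lowest reached -0.32. A scaling factor shared by all genes is argued against by the cilia median lying at -0.59 relative to all genes; the median of -0.88 with total counts only decides nothing, as that scaling lowers all genes. Depth is argued against by -0.68 after thinning all libraries to the lowest total. Fewer ciliated cells or less transcription per cell may both account for the fall, and neither was tested.

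The second pattern is the rise of 1 nanos and both DDX4 genes. Scaling is argued against, as the lowest of these changes was still 0.78 with total counts only. A loss of other cells stays open: the upper quartile of cytosolic ribosomal proteins was 0.35, below the lowest of the changes at 1.01, but every cell makes these proteins, so their level would not follow such a loss. This loss, more germ cells and more RNA per germ cell could each give the rise, and they cannot be told apart because whole embryos were measured. The germline list as a whole did not rise with these genes. Of its 29 measured genes 12 rose and 4 fell, a piwi-like gene and CPEB among those that fell. The median was 0.13, or -0.09 with total counts only, and camera gave no call. In which cells these genes were expressed was not measured.

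The third pattern is the difference of recovery embryos from day 4 controls. A part of rRNA or RNA quality stays open: leaving out rRNA genes gave 2793 genes against 2789 but moved the call of 0 of 829 named values, so it tests little, and the recovery libraries held 2.02% and 1.34% rRNA, between the 0.69% and 3.2% of the day 4 controls. Effects of BAPN that stayed are left open. Of the 1824 genes called in recovery and in blastula to day 2, 34.4% went the same way in both. This share cannot decide, as the blastula to day 2 change went with the day 3 to day 4 change of controls in 68.8% of shared calls. With blastula to day 4, which shares the day 4 controls, 73.5% of shared calls went the same way. With the controls divided, 963 went the same way and 317 the opposite way in 1 division, and 875 and 310 in the other. An earlier stage may account for much of the difference from day 4 controls, as a hypothesis found and tested on these libraries. Against day 3 controls 114 genes differed, a count from the fit of all 16 libraries that was not repeated in the other settings. Of 1312 genes also called between day 3 and day 2 controls, 95.1% changed in recovery opposite to the day 2 to day 3 change. That is the direction of a younger embryo, but it does not place recovery at day 3. The day 2 to day 3 change uses no recovery or day 4 library, while the calls judged by it do. These values do not tell slower development from a collection earlier than the labels say. The 114 genes stay open. Of them 104 were also called in blastula to day 2, a larger share than the 7264 of all 17519 tested genes called there. Of these 104, 45 went the same way and 59 the opposite way, or 43.3% the same way.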

How the results depend on the processing

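Total counts as the only scaling, the counts without rRNA genes, the lists as first written, recovery against day 3 controls and the divided day 4 controls were chosen after seeing the data. Across the settings run, named genes had 21324 values, of which 21064 stayed on their side of the threshold, 223 no longer passed and 37 newly passed. None of the 19307 values of called genes changed sign, and 85 of the 2017 values of genes not called did. Counts of genes in settings not given below stayed within 1.5 times. The cause of a change was not tested unless a setting's construction gives it.

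Requiring an absolute log2 change of at least 1 lowers counts by construction, to 5655 for the mean effect, 3412 for gastrula to day 3, 1223 for recovery, 1191 for the blastula against the gastrula start, 1291 for day 3 against day 2 controls, 1029 for day 4 against day 3 controls and 1 for dose. Fitting only the groups compared takes the spread from those groups alone. It gave 5240 for recovery (2770 of the 2789 genes among them, called the same way). Day 4 against day 3 controls rose from 2407 to 5895, while the 2 starts fell from 2479 to 1386. The main fit shares 1 estimate of the spread, but groups differed in the chi-square per degree of freedom between their 2 libraries. It was 5.26 in day 3 controls, 9.9 in recovery, 13.09 in gastrula to day 4, 19.34 in day 4 controls and 24.67 in blastula to day 4. Whether this moved the counts was not tested. Recovery against day 3 controls gave 114 genes, of which 79 were called the same way and 9 the opposite way against day 4 controls. Genes called the same way in recovery and blastula to day 4 numbered 963 and 875 with 1 day 4 control library for each comparison, in the 2 possible divisions, against 1589 with both shared; single controls leave less power. For dose, DESeq2 gave 55, no filter 126 and total counts only 2, against 4 with edgeR. For dose minus the controls, where edgeR gave 0, DESeq2 gave 3, DESeq2's size factors 1, no filter 72, total counts only 1 and counts without rRNA genes 1.

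Camera called 7, 6, 10, 7, 6 and 9 lists for the mean effect, blastula to day 2, gastrula to day 3, blastula to day 4, gastrula to day 4 and recovery. With an estimated correlation it called 0, 0, 0, 1, 0 and 2. Fry, which asks another question, called 20, 16, 17, 18 and 17 for the first 5.

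Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 9436 to 10352 genes for the mean effect, 6081 to 7752 for blastula to day 2, 4052 to 6066 for gastrula to day 3, 7376 to 9415 for blastula to day 4, 6329 to 8482 for gastrula to day 4, 1559 to 3247 for recovery, 6798 to 8895 for recovery against blastula to day 4, 1262 to 3095 for the 2 starts, 3718 to 5055 for day 4 minus day 2, 1340 to 3388 for day 3 against day 2 controls, 1205 to 2826 for day 4 against day 3 controls, 0 to 14 for dose and 0 to 1 for dose minus the controls.

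The labels name a control for each of 6 treated libraries but not what a pair shares. With these pairs as a block 9577 genes were called for the mean effect and 4182 for day 4 minus day 2, and the deviations of treated and named control libraries had correlations of 0.01, -0.01 and 0.02 in the 3 windows, so they do not show a culture shared within pairs, nor exclude one. In simulated data with 2 libraries per group 46% of 2-fold changes were recovered in a single window. Those data had 100 genes changed 2-fold and 100 changed 4-fold, while the real windows called 5633 to 9054 genes. The adjusted p is stricter where few genes change, so this share does not give the power in the real windows. That power is not known, and genes not called are not shown to be unchanged.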

Other observations

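The protein families below, the test of a delay against development and the choice of families to name came after results had been seen.

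Families of protein domains with at least 10 measured genes, 186 in all, were tested for the mean BAPN effect with camera. Ligand-gated ion channel genes (Neur_chan_LBD), which serve synapses, fell in 23 and rose in 1 of 40 (median -2.71; adjusted p = 1.3e-05, and adjusted p = 0.4 with an estimated correlation). Glucuronosyltransferases (UDPGT), which make foreign compounds soluble, fell in 20 and rose in 0 of 26 (median -1.76; adjusted p = 3.7e-05). Dynein heavy chains fell in 18 and rose in 0 of 19 (median -0.95; adjusted p = 3.8e-05, and adjusted p = 0.5 with an estimated correlation). Proteasome subunits, which degrade proteins, fell in 14 and rose in 0 of 14 (median -0.86; adjusted p = 9.1e-05). Short-chain dehydrogenases fell in 56 and rose in 9 of 93 (median -1.23; adjusted p = 0.00042), sulfotransferases fell in 48 and rose in 5 of 73 (median -1.12; adjusted p = 0.00045) and glutathione transferases fell in 13 and rose in 2 of 18 (median -2.86; adjusted p = 0.0015). Transcription factors of the bZIP_2 family rose in 12 and fell in 1 of 13 (median 1.98; adjusted p = 0.00072), and ABC transporter genes of the ABC_tran family rose in 13 and fell in 3 of 22 (median 1.03; adjusted p = 0.0012). Those of the larger ABC_membrane family moved both ways, with 20 rises and 15 falls in 43 (median 0.26; adjusted p = 0.12, no call). With an estimated correlation the adjusted p of all families called here lay between 0.4 and 0.5, so none of these calls held.

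A delay of treated embryos was tested as a hypothesis for the BAPN effect at day 4. Across genes, which are not independent replicates, the change in blastula to day 4 had a correlation of -0.27 with the change of controls from day 2 to day 3, which shares no library with it. Of the genes called in both, 1635 went in opposite ways and 558 the same way (25.4%), and for gastrula to day 4 1403 went in opposite ways and 616 the same way (30.5%), with a correlation of -0.22. For day 2 only a later change of controls was at hand, which cannot show or exclude a delay at that day. Blastula to day 2 and the change of controls from day 3 to day 4, which share no library, had 1111 genes called the same way. In opposite ways went 504 (68.8% the same way, correlation 0.05). The 2 day 4 correlations lie above -0.3, the side set for excluding a delay, while the day 4 calls run toward one. Cell cycle genes went against a delay. In controls their median change was -0.23 from day 2 to day 3 and -0.28 from day 3 to day 4. In BAPN it was -1.47 in blastula to day 4 and -2.03 in gastrula to day 4, a fall that a delay between these days would not give. A delay at day 4 may thus contribute for other genes and stays open. No control was collected before day 2, and an earlier stage than that was not analysed here.

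The groups of libraries were also regrouped. For the mean effect, refitted on the 12 libraries of the 3 windows, 100 of the 108 splits of treated and control libraries within days were drawn. Only 1 of them, the real one, reached its count, with 10131 genes against 5668 in the highest other. An arbitrary division of these libraries is thus argued against, though 1 of 100 is the smallest share this draw can give. Differences between cultures are not covered, as the labels do not say which libraries came from separate cultures. Swapping doses within windows gave 16 splits, too few for a share under 0.05; the real one called 4 genes and the highest other 1. For dose minus the controls 4 of 4 splits called as many, with 0 in the real one and 0 in the highest other, and these are too few for a share under 0.05.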
